A study of Homo sapiens with 8 samples.

How the data were processed

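Ribosome profiling was done in U2OS cells, an established human osteosarcoma line, that carried either an empty vector or a construct for QKI7, an isoform of the RNA-binding protein QKI. All cells had been exposed to 0.5 mM sodium arsenite for 1 h, a treatment that causes oxidative stress and the assembly of stress granules. Each culture condition gave input RNA libraries, from which ribosomal RNA had been depleted, and libraries of ribosome-protected fragments of 17 to 34 nt, called footprints here. Groups were taken from the sample labels and make 4 groups of 2 libraries each (vector input, QKI7 input, vector footprint and QKI7 footprint), read as single 51 nt reads per the labels. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. No untreated cells were analysed here, so no comparison bears on arsenite itself.

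The authors deposited 1 table of TPM, a measure of transcript share corrected for length, for 26902 genes and RNAs in the 8 libraries, with 2 decimals. The submitters' processing notes name STAR, RSEM 1.2.31 and the GRCh38 build, without saying which step used which settings; whether reads were counted by strand is not given in the sources used here. The deposited TPM of each library are shared by all entries of the table, including ribosomal RNA, small non-coding RNA and 92 synthetic ERCC spike-ins. TPM keeps no read depth, so the number of reads behind a value is unknown, no counting interval is given, and a value of 0 is described as listed at 0. Of the entries, 23970 matched a symbol of the RefSeq annotation of GRCh38 (assembly GRCh38.p14), 1395 matched through an older symbol and 1537 had no match, among them the spike-ins; RNA classes and coordinates come from that match.

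The main test was limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend) on log2(TPM + 1) for the 5806 entries with a mean of at least 1 TPM over the 8 libraries, in a fit of 4 group means with 4 residual degrees of freedom. Contrasts were QKI7 against vector in inputs (RNA level), QKI7 against vector in footprints (footprint level), the interaction of library type and construct (translation efficiency) and footprint against input within each construct. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all entries, with 0.05 as the threshold. Log2 changes are on the log2(TPM + 1) scale, which understates the change of low values. With 2 against 2 libraries an exact permutation test cannot go below 0.333, so calls rest on the variance that limma shares between genes.

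Messenger RNA makes up a small part of the deposited TPM, so the pseudocount weighs on footprint values and a change of the mRNA share shifts all mRNAs together. Changes of gene groups are therefore given relative to the median of all entries tested. A second scale, called the mRNA scale, is printed beside the main values where it changes a call, a direction or a split: 2654 entries (spike-ins, histone genes and small non-coding RNA) were removed and the rest rescaled to equal sums. It tests 16652 genes at a mean of at least 1 rescaled TPM. Many of these have footprints near the 2-decimal rounding of the deposited values. Over all 18713 mRNA entries, the median as deposited was 0.02 TPM in each vector and 0.03 TPM in each QKI7 footprint library. Of these entries, 3239 had a mean footprint of at least 0.2 TPM. A narrower version, chosen after seeing the data, keeps the 2791 genes with a mean of at least 1 TPM in inputs and 0.2 TPM in footprints as deposited.

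A total of 25 gene lists were fixed before the data were examined, along with the tests, the rule for named genes and most alternatives. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, and with fry. Of these lists, 21 had at least 3 members tested. The mitochondrially encoded mRNAs were not analysed here, and the marker lists of blood, epithelial and neural cells had 0 tested members. Genes named for the QKI7 contrasts are the 10 largest changes per direction among those past the threshold whose QKI7 libraries both lie outside the range of the vector libraries; for footprint against input, the 10 highest and 10 lowest with a mean of at least 10 TPM. For each list described, up to 4 members past the threshold are named by size of change, and QKI, ATF4, PPP1R15A, G3BP1, YAP1 and TEAD1 are always considered. The same rule was run on the mRNA scale.

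The fit was tested on simulated data with the means and spread of the 5806 entries and 100 entries changed at each size, drawn from those at about 1 TPM or more. A log2 change of 1 was recovered for 100% of entries changed in the inputs and 95% of those changed in the footprints, and a log2 change of 0.5 for 92% and 79%. For translation efficiency, a change of 0.5 made in the footprints was recovered for 32% of entries and a change of 1 for 90%. False calls made up 3.52% to 5.43% of calls in these simulations, which had independent noise for each entry and no shift shared by all entries. The rates in the data, where such a shift was present, may differ. The recovery rates do not cover changes of footprints well under 1 TPM.

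Alternatives fixed in advance were pseudocounts of 0.1 and 5, no filter on low values, a mean of at least 10 TPM, median-of-ratios scaling, quantile normalization, the mRNA scale, a prior variance without trend, fits of only the 4 libraries compared, replicate blocks and leaving out each library in turn. Scaling of the inputs to the spike-ins was added after seeing the data. A search for QKI motifs in 3' untranslated regions was not run, because no sequences were used here.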

Results

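The series measured input RNA and ribosome footprints in arsenite-treated U2OS cells, an osteosarcoma line, with an empty vector or with overexpressed QKI7. QKI7 is an isoform of QKI, an RNA-binding protein of the STAR family with roles in splicing, RNA stability and translation. The series title names the effect of QKI7 on translation efficiency as its subject. There were 2 input and 2 footprint libraries per construct. Replicate libraries correlated at Pearson r = 0.993 for vector inputs, 0.990 for QKI7 inputs, 0.995 for vector footprints and 0.994 for QKI7 footprints, across the 5806 entries tested, which are not independent of each other.

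The libraries held mostly RNA other than mRNA. In inputs, 7SL RNA, the RNA of the signal recognition particle, took 48.3% ± 0.921 of all TPM in vector cells and 47.2% ± 0.792 in QKI7 cells (SD, n = 2 each). Small nuclear RNA took 33.2% ± 0.0811 and 33.0% ± 2.91, and the spike-ins 13.9% ± 0.793 and 14.5% ± 1.95. Messenger RNA took 3.85% ± 0.197 of vector inputs and 4.37% ± 0.198 of QKI7 inputs, a ratio of 1.13. In footprints, ribosomal RNA took 97.3% ± 0.0134 in vector cells and 96.8% ± 0.0404 in QKI7 cells, and mRNA took 0.628% ± 0.00218 and 0.613% ± 0.00469. The number of reads behind these shares is unknown.

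**Figure D1:**
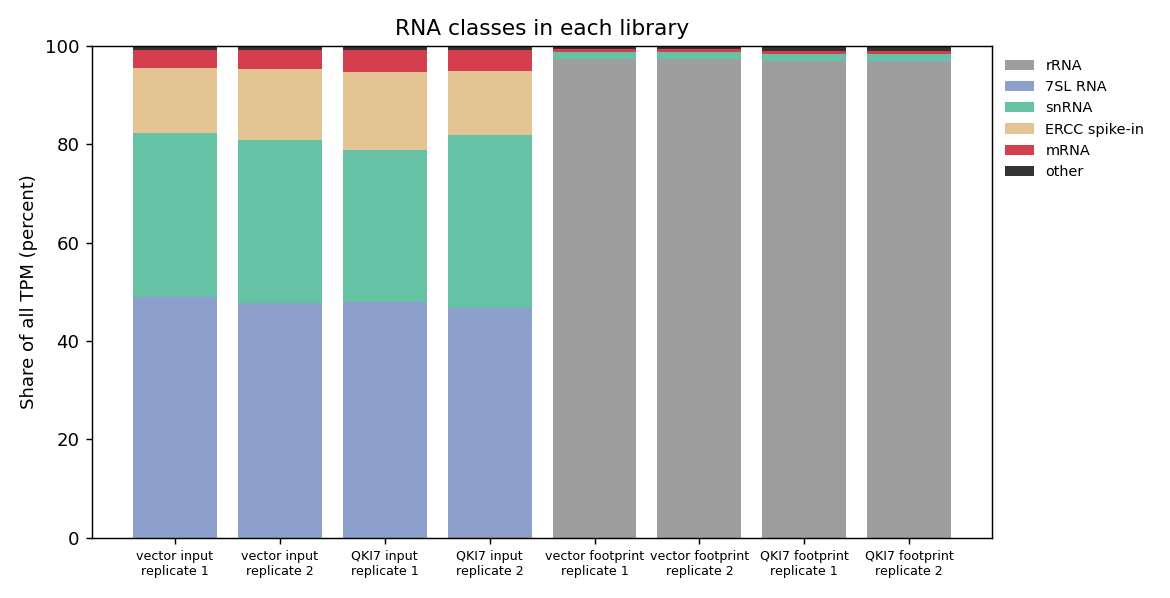
Share of all TPM (percent, vertical axis) taken by each RNA class in the 8 libraries (bars). Inputs were mostly 7SL RNA, small nuclear RNA and spike-ins, and footprints mostly ribosomal RNA (97.3% in vector and 96.8% in QKI7 cells); mRNA took 3.85% of vector and 4.37% of QKI7 inputs.

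QKI itself (Entrez gene 9444, chromosome 6, 163414718 to 163578592 in GRCh38) was raised in every QKI7 library. Its input level was 3.23 ± 0.311 TPM in vector cells and 1664 ± 119 TPM in QKI7 cells (SD, n = 2 each), a 515-fold difference and a log2 change of 8.62 (SE 0.094, adjusted p = 1.85e-09). In footprints it was 0.615 ± 0.0636 and 27.5 ± 0.750 TPM, a 44.8-fold difference (log2 change 4.14, adjusted p = 5.88e-07). The footprint gain was thus smaller than the RNA gain, and QKI had the most negative translation efficiency change among the named genes, -4.48 (SE 0.133, adjusted p = 4.84e-06), or -3.30 on the mRNA scale. Values per gene do not separate QKI7 from other QKI isoforms, nor the coding part of the construct from any other transcribed part.

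**Figure D2:**
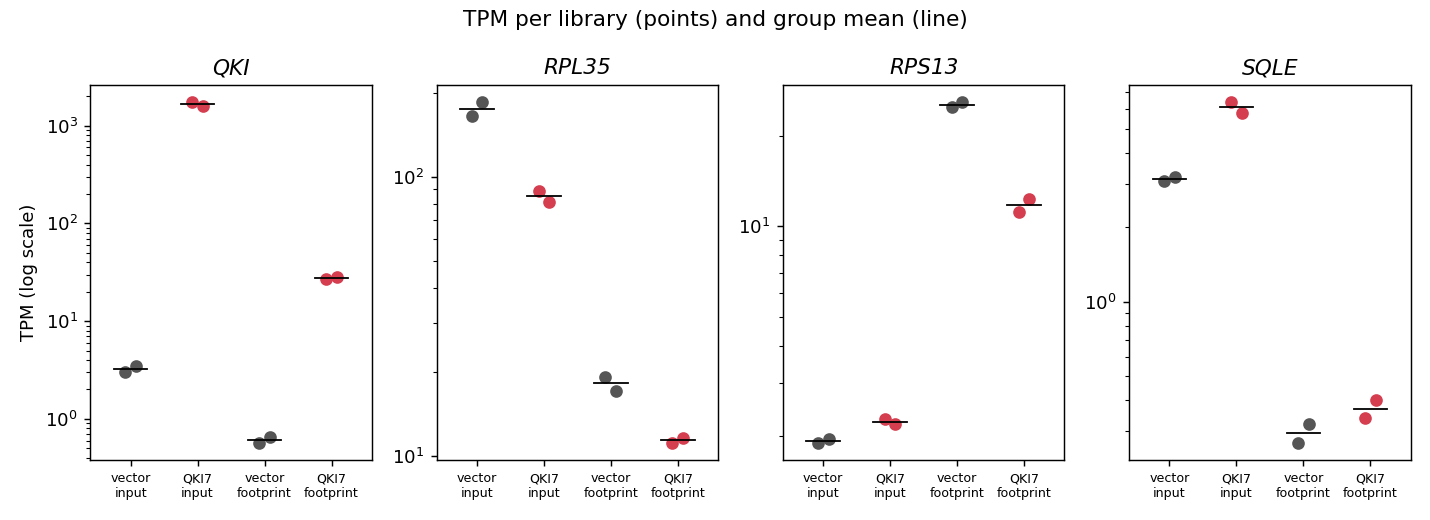
TPM (vertical axes, log scale) of QKI, RPL35, RPS13 and SQLE in each library, with vector libraries in grey and QKI7 libraries in red; points are libraries and lines are group means. QKI rose from 3.23 to 1664 TPM in inputs and from 0.615 to 27.5 TPM in footprints.

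The comparison of inputs asks which RNAs changed in level with QKI7. Ribosomal protein mRNAs were lower in QKI7 cells and cholesterol synthesis mRNAs were higher. Of 77 ribosomal protein genes, 47 fell and 1 rose, with a median 0.48 below that of all genes on the log2 scale (relative change -0.48; camera adjusted p = 2.43e-36). RPL35, of the large subunit (chromosome 9, 124857883 to 124861957), fell from 175 ± 14.4 to 85.0 ± 5.49 TPM (SD, n = 2 each; log2 change -1.03, SE 0.104, adjusted p = 0.00117). RPL38 fell by 0.94 (adjusted p = 0.00117), RPS15 by 0.87 (adjusted p = 0.00177) and RPL36A by 1.17 (adjusted p = 0.00252) on the log2 scale. The 12 tested genes of cholesterol synthesis and uptake all rose, with a relative median of 0.34 (camera adjusted p = 0.000371). Among them SQLE, squalene epoxidase, went from 3.14 ± 0.0849 to 6.10 ± 0.424 TPM (log2 change 0.78, adjusted p = 0.000885). HMGCS1 and MVD rose by 0.66 and 0.62 (adjusted p = 0.00154 and 0.00131). With an estimated correlation the 2 lists had an adjusted p = 0.153 and an adjusted p = 0.292; on the mRNA scale these were 0.000366 and 0.0121. For single genes the mRNA scale made fewer calls: RPL35, RPL38 and RPS15 passed (adjusted p = 0.00254, 0.000501 and 0.00515), while RPL36A and SQLE did not (adjusted p = 0.118 and 0.111), and 0 of 20 cholesterol genes passed.

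Other stress and growth programmes moved less. Nuclear genes of the respiratory chain had a relative median of -0.16, with 12 of 55 lower and 3 higher (camera adjusted p = 2.69e-08). The mRNA of ATP5E, a subunit of ATP synthase, fell by 0.77 and that of UQCR10, a subunit of complex III, by 0.61 (adjusted p = 0.00299 and 0.000955). Translation factors stood at -0.21 (7 of 36 lower, 2 higher; camera adjusted p = 6.31e-06); the elongation factor EEF2 fell by 0.38 (adjusted p = 0.00804) and EIF4A3 by 0.38 (adjusted p = 0.00576). Targets of ATF4, the transcription factor of the integrated stress response, stood at -0.17 (3 of 17 lower, SESN2, SARS and SHMT2; camera adjusted p = 7.46e-05). The NF-kappaB list stood at -0.27 (3 of 7 lower, TNFAIP3, NFKBIA and RELB; camera adjusted p = 0.000516). ER chaperones stood at -0.16 (3 of 17 lower and 4 higher; camera adjusted p = 0.00705): HSPA5, the main chaperone of the ER lumen, fell by 0.41 (adjusted p = 0.00469) while DNAJB11 rose by 0.40 (adjusted p = 0.00837). Replication-dependent histone genes stood at -0.12 (2 of 40 lower and 4 higher; camera adjusted p = 0.0035), with HIST1H4A 0.40 higher (adjusted p = 0.00336) and HIST1H4J 0.37 lower (adjusted p = 0.0111). Mitosis and S phase genes stood at 0.12 (24 of 38 higher, 1 lower; camera adjusted p = 0.0122), with CENPE, a kinetochore motor, and ASPM, a spindle pole protein, 0.59 higher each (adjusted p = 0.00208 and 0.00177). With an estimated correlation, these 7 lists had an adjusted p = 0.153 (respiratory chain), 0.502 (translation factors), 0.166 (ATF4 targets), 0.292 (NF-kappaB), 0.527 (ER chaperones), 0.166 (histones) and 0.722 (mitosis). By fry, which asks whether a list changed without comparing it to other genes, the adjusted p was 0.00812 for ribosomal proteins, 0.00235 for cholesterol, 0.0366 for NF-kappaB and 0.0124 for mitosis, but 0.1004 for the respiratory chain, 0.303 for translation factors, 0.0977 for ATF4 targets, 0.264 for histones and 0.565 for ER chaperones. Fry also passed lists that camera did not call, among them heat shock (adjusted p = 0.0148) and extracellular matrix genes (adjusted p = 0.00274), a test that includes the shift of 0.15 of all entries. Leaving out 1 library ended 3 of the 9 list calls in 1 fit each: histones without vector input replicate 1 (camera adjusted p = 0.0807), and ER chaperones and mitosis without vector input replicate 2 (0.0516 and 0.0586).

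Counted over the list alone, adjusted p fell under the threshold for 47 lower ribosomal protein genes, 12 higher cholesterol genes, 26 higher mitosis genes, 9 lower respiratory chain genes, 7 lower translation factors, 3 lower members each of the ATF4, NF-kappaB and ER chaperone lists, and 2 higher and 1 lower histone genes. On the mRNA scale 0 of 42 mitosis genes passed over all genes. The other 12 lists were not called in inputs (camera adjusted p from 0.0615 to 0.997). Of these, heat shock genes had 10 of 17 members higher, such as HSPH1 (log2 change 0.69, adjusted p = 0.00119) and DNAJB1 (0.61, adjusted p = 0.00133), with a relative median of 0.23 (camera adjusted p = 0.109). Hippo pathway genes stood at 0.011 (10 of 22 higher; camera adjusted p = 0.332); YAP1 and TEAD1, the coactivator and DNA-binding factor of the pathway, were 0.23 and 0.41 higher (adjusted p = 0.00868 and 0.00304), calls that the mRNA scale did not make (adjusted p = 1.00 and 0.803). YAP target genes stood at -0.11 (5 higher, 4 lower of 15; camera adjusted p = 0.0615), with CTGF and ANKRD1 lower (adjusted p = 0.00561 and 0.0180). Stress granule proteins (0.0011; 11 higher and 2 lower of 28; camera adjusted p = 0.997), m7G and m6A machinery (-0.046; camera adjusted p = 0.981), p53 targets (-0.051; adjusted p = 0.279), interferon-stimulated genes (-0.05; adjusted p = 0.0745), extracellular matrix genes (0.10; adjusted p = 0.279), NRF2 and metal response genes (-0.033; adjusted p = 0.326), immediate early genes (0.10; adjusted p = 0.65), uORF-controlled stress mRNAs (-0.08; adjusted p = 0.405) and RNAs named as QKI targets in earlier work (0.09; adjusted p = 0.927) were not called either.

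Among single genes outside these lists, MIF, a cytokine, fell from 2.72 ± 0.339 to 0.830 ± 0.382 TPM (log2 change -1.04, adjusted p = 0.00200), a call the mRNA scale did not make (adjusted p = 0.0793). IFITM3, an interferon-induced membrane protein, fell from 7.21 ± 1.18 to 3.24 ± 0.311 TPM (log2 change -0.95, adjusted p = 0.00138). ATF4, PPP1R15A and G3BP1 differed by 0.03, -0.09 and 0.15 and were not called (adjusted p = 0.789, 0.452 and 0.186). The largest rises after QKI were in fragments of non-coding RNA. SNORD57 and SNORD116-4 were listed at 0 in both vector inputs and at 1.69 and 4.38, and 1.58 and 2.36 TPM, in the QKI7 inputs. The 28S and 18S ribosomal RNA left after depletion rose by 1.45 and 1.24 (adjusted p = 0.00674 and 0.0128 for RNA28S5 and RNA18S5), and RNA5-8S5 by 1.09 (adjusted p = 0.0081). Most of this rise was in QKI7 input replicate 2: RNA18S5 had 230 TPM in replicate 1 and 511 TPM in replicate 2, and leaving out 1 library gave 0.67 to 1.81 for RNA18S5 (call lost in 1 fit) and 0.88 to 2.02 for RNA28S5. The precursors MIR937, MIR941-1, MIRLET7D and MIR3687-1 rose by 1.54, 1.21, 1.13 and 1.04 (adjusted p = 0.00837, 0.0121, 0.00653 and 0.00468); MIR3687-1 has an identical copy and ribosomal RNA genes are repeated, so their values are uncertain. SNORD32A, SNORD68, SNORD63, SNORD58A and MIR4449 fell by 1.70, 1.69, 1.14, 1.04 and 1.29 (adjusted p = 0.0126, 0.0106, 0.0403, 0.0122 and 0.0371), and SNORD4A was listed at 0 in both QKI7 inputs against 0.86 and 1.51 TPM in the vector inputs. Without 1 library in turn, the change ranged from -2.42 to -0.96 for SNORD68 and 0.70 to 1.56 for MIRLET7D. For MIR941-1 it was 0.78 to 1.65, and for RNA5-8S5 0.69 to 1.48. Leaving out 1 library ended the calls of MIR4449 and SNORD63 in 3 fits each, of SNORD32A and SNORD58A in 2 each and of SNORD68 in 1, and that of MIR941-1 in 2, with ranges of 0.94 to 2.15 for MIR937, -2.02 to -0.57 for MIR4449 and -1.75 to -0.52 for SNORD63. Of 54 named genes called in inputs, 40 were called in every such fit.

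In all, 2587 of 5806 entries passed the threshold, 2269 higher and 318 lower, and the median change of all entries was 0.15. That split followed the scale: on the mRNA scale 99 of 16652 genes passed, 8 higher and 91 lower, median-of-ratios scaling gave 738 higher and 1367 lower, and quantile normalization 1082 higher and 928 lower. Inputs scaled to the spike-ins, an alternative added after seeing the data, kept most calls higher, at 1470 against 311 lower. Without QKI7 input replicate 1 the count was 1685.

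The footprint comparison asks which mRNAs carried more or fewer ribosome-protected fragments with QKI7. Ribosomal protein mRNAs were again lower: 52 of 77 fell and 1, RPS2, rose, with a relative median of -0.47 (camera adjusted p = 1.91e-41). RPS13, of the small subunit, fell from 25.4 ± 0.721 to 11.7 ± 0.799 TPM (SD, n = 2 each; log2 change -1.05, SE 0.072, adjusted p = 0.000176), and RPS12 from 23.7 ± 0.141 to 10.7 ± 0.325 TPM (log2 change -1.07, adjusted p = 0.00366). RPL35A and RPS15A fell by 1.02 and 1.00 (adjusted p = 0.000221 and 0.00039). Respiratory chain genes had a relative median of -0.25, with 18 of 55 lower and 0 higher at the adjusted threshold (camera adjusted p = 5.1e-12). COX6A1, a subunit of cytochrome c oxidase, fell from 9.31 ± 0.184 to 4.80 ± 0.177 TPM (log2 change -0.83, adjusted p = 0.001) and NDUFB9, of complex I, by 0.88 (adjusted p = 0.0039). Translation factors stood at -0.23 (10 of 36 lower, 1 higher; camera adjusted p = 7.74e-08), with EIF3I 0.61 lower (adjusted p = 0.0026). With an estimated correlation the 3 lists had an adjusted p = 0.0933, 0.0933 and 0.623; on the mRNA scale these were 0.00257, 0.0106 and 0.0216.

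Stress response mRNAs made smaller shifts. ER chaperones stood at -0.16 (2 of 17 lower, HSPA5 and PDIA6; camera adjusted p = 0.00608), ATF4 targets at -0.11 (4 of 17 lower, ASNS, SHMT2, GARS and SARS; camera adjusted p = 0.011) and uORF-controlled stress mRNAs at -0.10 (2 of 14 lower; camera adjusted p = 0.0207). ASNS, asparagine synthetase, fell from 0.870 ± 0.0141 to 0.380 ± 0.0283 TPM (log2 change -0.44, adjusted p = 0.00196). In the uORF list the members that fell were EIF1, a factor of start codon selection (10.7 ± 0.530 to 5.61 ± 0.658 TPM, log2 change -0.83, adjusted p = 0.00159), and C19orf48 (-0.32, adjusted p = 0.0144). Leaving out 1 library ended the calls of PDIA6 and GARS in 6 of 8 fits and those of HSPA5 and SARS in 4, and 25 of 36 named genes called in footprints were called in every such fit. C19orf48 lost its call in 3 fits, and the uORF list in 2 (camera adjusted p up to 0.136, relative median -0.049). These lists had an adjusted p = 0.664, 0.615 and 0.704 with an estimated correlation. By fry the adjusted p in footprints was 0.00426 for ribosomal proteins and 0.00805 for the respiratory chain, but 0.0775 for translation factors, 0.135 for ER chaperones, 0.0663 for ATF4 targets and 0.135 for uORF-controlled mRNAs. Adjusted over the list alone, 66 ribosomal protein, 25 respiratory chain and 17 translation factor genes were lower, with 4 ER chaperone, 5 ATF4 target and 4 uORF-controlled genes. The other 15 lists were not called (camera adjusted p from 0.225 to 0.936), among them Hippo pathway genes (relative median 0.03, adjusted p = 0.255) and stress granule proteins (-0.04, adjusted p = 0.367). ATF4, G3BP1, PPP1R15A, YAP1 and TEAD1 had changes of -0.25, -0.28, -0.10, 0.04 and 0.09 (adjusted p = 0.0931, 0.106, 0.72, 0.825 and 0.612); on the mRNA scale ATF4, G3BP1 and TEAD1 passed, at -0.25, -0.42 and 0.78 (adjusted p = 0.022, 0.0286 and 0.0159).

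The tubulin genes TUBA1C and TUBA1B fell by 1.00 and 0.97 in footprints (adjusted p = 0.00387 and 0.00216), and FABP5, a fatty acid carrier, from 7.07 ± 0.431 to 2.90 ± 0.488 TPM (log2 change -1.05, adjusted p = 0.000644). NME1-NME2 and ATP5EP2 fell by 1.01 and 1.05 (adjusted p = 0.0134 and 0.00126), but they overlap or copy other genes and their values are uncertain. Footprint-sized reads of RELN, which encodes a secreted glycoprotein, rose from 91.1 ± 5.55 to 638 ± 0.290 TPM (log2 change 2.79, adjusted p = 1.27e-06), while its inputs held 0.0300 ± 0.0141 TPM in each construct. GRK3, a receptor kinase, rose from 3.44 ± 0.354 to 22.0 ± 4.51 TPM (log2 change 2.36, adjusted p = 6.76e-05), and DICER1, the endonuclease that makes microRNAs, from 11.8 ± 0.757 to 63.8 ± 2.98 TPM (log2 change 2.34, adjusted p = 7.44e-06). Small RNAs also rose: SNORA4, SNORA13, MIR663A and MIR21 by 2.31, 1.99, 2.20 and 2.11 (adjusted p = 0.00799, 0.000815, 0.000499 and 0.000511). SNORD10 fell by 1.19 (adjusted p = 0.000815). RNU6-2 and RNU6-9, copies of U6 with equal values, were at 0 and 0.01 TPM in vector footprints and at 23.95 and 55.99 TPM in QKI7 footprints, and are uncertain for the same reason.

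In footprints 476 entries passed the threshold, 209 higher and 267 lower. Among those matched to protein-coding genes, 97 were higher and 252 lower. Spike-ins, histone genes and small non-coding RNA together made up 105 of the higher and 7 of the lower entries. On the mRNA scale 1999 genes passed, 1337 higher and 662 lower, or 382 and 588 for those measured in both library types. The wider set holds many genes with footprints near the rounding of the deposited values, so its split is uncertain. Median-of-ratios scaling gave 225 higher and 439 lower, quantile normalization 216 and 336, a pseudocount of 0.1 677 and 447, a mean of at least 10 TPM 117 and 90, and only the 4 libraries compared 56 and 18; leaving out any 1 of the 4 footprint libraries gave 253 to 299.

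Changes of RNA and footprints were positively related across genes, to an extent that depends on the genes tested and the scale (Pearson r = 0.25, Spearman rho = 0.22, covariance 0.0193, 5806 entries, no shared libraries; genes are not independent replicates). Pearson r was 0.48 at a mean of at least 10 TPM, 0.17 without a filter and 0.10 on the mRNA scale. All these sets include the overexpressed QKI itself, 515-fold higher in inputs and 44.8-fold in footprints. This 1 entry raises Pearson r and the covariance, most where few entries were tested, as at 10 TPM. Values without QKI were not computed, so the 0.48 need not describe the other genes. The ribosomal protein list was lower in both measures, and its translation efficiency stood at the median of all genes (relative median 0.0085, camera adjusted p = 0.545). A total of 86 entries were lower in both inputs and footprints, against 14.6 for independent lists, and 48 were higher in both, against 81.7. The latter shortfall was not seen with other scales and gene sets together: on the mRNA scale 3 were higher in both against 0.642, and 11 against 3.70 for genes measured in both library types, while 66 and 137 were lower in both against 3.62 and 46.6. The cholesterol and mitosis lists were called in inputs and not in footprints (relative medians 0.066 and -0.011, camera adjusted p = 0.291 and 0.336); in inputs they had an adjusted p = 0.292 and 0.722 with an estimated correlation.

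**Figure D3:**
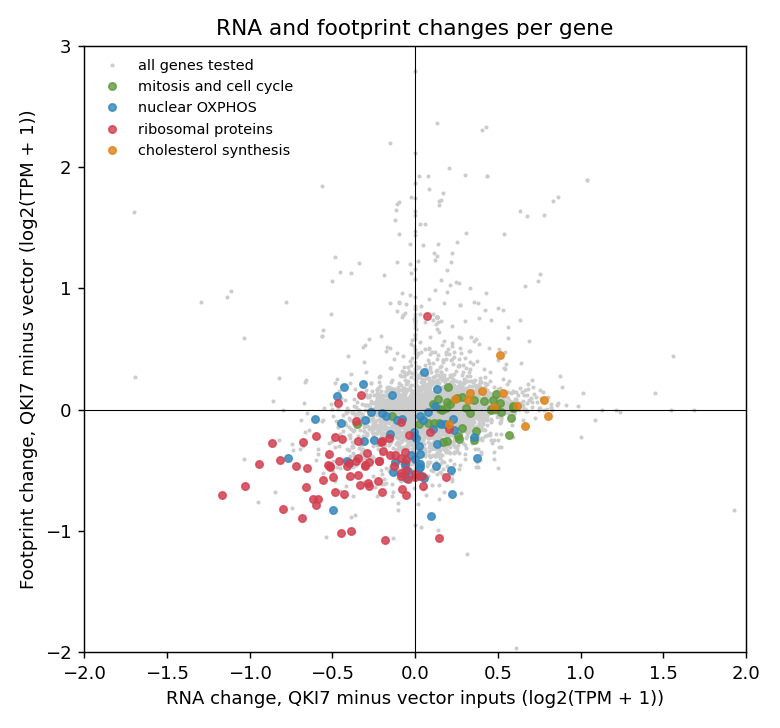
Log2 change of footprints (vertical axis) against log2 change of input RNA (horizontal axis), QKI7 minus vector on the log2(TPM + 1) scale, for each gene tested (points), with 4 gene lists in colour. Ribosomal protein genes lie mostly to the lower left (47 of 77 lower in RNA, 52 lower in footprints) and cholesterol genes to the right (12 of 12 higher in RNA); 4 entries lie outside the axes, and zero on each axis moves with the scaling of the libraries.

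On the deposited scale, translation efficiency, the footprint change beyond the RNA change, was lower in QKI7 cells for cholesterol and mitosis genes. Of 12 cholesterol genes, 7 fell and 0 rose at the adjusted threshold, with a relative median of -0.20 (camera adjusted p = 0.0141). HMGCS1 fell by 0.79 (SE 0.118, adjusted p = 0.00844). SQLE and MVD fell by 0.70 and 0.58 (adjusted p = 0.00631 and 0.0114). Of 38 mitosis and S phase genes, 19 fell, with a relative median of -0.19 (camera adjusted p = 0.0141), among them UBE2C (-0.77, adjusted p = 0.0149), DLGAP5 (-0.64, adjusted p = 0.014), RRM1 (-0.61, adjusted p = 0.00937) and CENPE (-0.58, adjusted p = 0.0164). Footprints of HMGCS1, DLGAP5, RRM1, SQLE, MVD and CENPE were under 1 TPM in each library, so the pseudocount mutes their footprint changes and the RNA rise weighs more. For SQLE, MVD and CENPE, the values are then close to the RNA rise with its sign turned. Their plain TPM rose 1.25-, 1.125- and 1.08-fold in footprints, against 1.94-, 1.73- and 1.57-fold in inputs. Plain footprints of HMGCS1, UBE2C, DLGAP5 and RRM1 fell to 0.81, 0.77, 0.90 and 0.66 times those of vector cells. The NF-kappaB list stood at 0.28 (2 of 7 higher; camera adjusted p = 0.00206), with TNFAIP3, an inhibitor of the pathway, at 0.44 and RELB at 0.31 (adjusted p = 0.0109 and 0.0233). The sign of TNFAIP3 depends on the pseudocount: its footprints were 0.10 TPM in both vector libraries and 0.05 and 0.07 TPM in the QKI7 libraries, and its plain ratio of footprint to input TPM was 0.0199 in vector and 0.0184 in QKI7 cells. For RELB that ratio was 0.0382 and 0.0658, and for NFKBIA, another member, 0.0560 and 0.0393. Of these members only RELB rose by the plain ratio, so the higher list value need not mean more footprints per RNA. With an estimated correlation the 3 lists had an adjusted p = 0.886 (cholesterol), 0.935 (mitosis) and 0.886 (NF-kappaB); by fry the adjusted p was 0.0194, 0.0422 and 0.0678. The cholesterol and mitosis calls were each lost without vector input replicate 2 or QKI7 input replicate 2 (camera adjusted p up to 0.0732 and 0.0705), and leaving out 1 library ended the calls of RELB in 5 fits, CENPE in 4, DLGAP5 in 2 and UBE2C in 1. On the mRNA scale the relative medians were -0.48, -0.22 and 0.40 (camera adjusted p = 0.241, 0.0239 and 0.324), and 0 members of each list passed over all genes. Adjusted over the list alone, as deposited, 7 cholesterol and 22 mitosis genes were lower and 2 NF-kappaB genes higher.

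RPS13 had the largest fall among coding genes after QKI, -1.20 (SE 0.102, adjusted p = 0.00128), with inputs of 1.93 ± 0.0424 TPM in vector and 2.23 ± 0.0636 TPM in QKI7 cells. TUBA1C and TUBA1B, which encode alpha-tubulin, fell by 1.14 and 1.00 (adjusted p = 0.0104 and 0.00937), calls that the mRNA scale did not make (adjusted p = 0.0693 and 0.0855). RELN and GRK3 rose by 2.79 and 2.23 (adjusted p = 1.9e-05 and 0.00108). The remaining large changes were in non-coding RNA, to which translation does not apply: SNORA75 rose by 2.40, MIR663A by 2.35 and SNORD32A by 3.33, while SNORD57 fell by 2.75 and SNORD10 by 1.51 (adjusted p = 0.000754, 0.00402, 0.0117, 0.0177 and 0.00309). The plain ratio of footprint to input TPM of TEAD1 rose from 0.0230 in vector to 0.0284 in QKI7 cells, so the sign of its value here depends on the pseudocount. G3BP1, a core protein of stress granules, was 0.43 lower (adjusted p = 0.0392), and TEAD1 0.32 lower (adjusted p = 0.0432), at -0.39 and 0.49 on the mRNA scale (adjusted p = 0.169 and 0.244). Each call was lost in 6 of the 8 fits that leave out 1 library. ATF4, PPP1R15A and YAP1 were not called (-0.28, -0.01 and -0.19; adjusted p = 0.086, 0.957 and 0.0879). The other 18 lists were not called (camera adjusted p from 0.123 to 0.847), including YAP targets (0.20, adjusted p = 0.123), Hippo pathway genes (0.04, adjusted p = 0.847), stress granule proteins (-0.02, adjusted p = 0.661) and RNAs named as QKI targets (-0.11, adjusted p = 0.603).

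In all, 1461 entries passed for translation efficiency, 207 higher and 1254 lower, around a median of -0.16. On the mRNA scale 241 passed, 195 higher and 46 lower; median-of-ratios scaling gave 720 higher and 381 lower and quantile normalization 467 and 598, and leaving out any 1 of the 4 footprint libraries left 269 to 423 calls.

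Footprint against input asks which RNAs carried many or few footprints per RNA in stressed cells. In vector cells, the lists of replication-dependent histone genes and of respiratory chain genes were footprint-rich by this ratio, and the ferritin mRNAs FTH1 and FTL footprint-poor. The ratio varied widely within a list. Among ribosomal proteins, plain footprint-to-input TPM was 13.2 for RPS13 and 8.61 for RPS15A, but 0.0363 for RPL13A and 0.0802 for RPL4. Whether such differences come from translation or from how the 2 library types measure an RNA was not tested. Relative to the median of all entries (-1.81), histone genes stood at 3.90 (37 of 40 higher; camera adjusted p = 1.21e-64), respiratory chain genes at 1.96 (24 of 55 higher and 20 lower; camera adjusted p = 3.2e-27) and ribosomal protein genes at 1.84 (34 of 77 higher and 32 lower; camera adjusted p = 5.86e-25). HIST1H2AD was at 48.5 ± 0.445 TPM in footprints and at 0.45 and 0 TPM in the inputs, and HIST2H4A and HIST2H4B, identical copies, differed by 3.39 (adjusted p = 1.43e-08). COX7C, of cytochrome c oxidase, had 25.4 ± 0.318 TPM in footprints and 1.87 ± 0.0283 TPM in inputs (log2 difference 3.20, adjusted p = 9.39e-10). The NRF2 and metal response list stood at 1.05 (4 of 11 higher and 6 lower; camera adjusted p = 0.0111), turning to -0.34 without a filter and -0.82 at a mean of at least 10 TPM, and its largest differences were lower ones: FTH1 and FTL, the ferritin chains, at -5.25 and -4.38 (adjusted p = 5.2e-10 and 8.3e-10), the zinc exporter SLC30A1 at -4.08 and HMOX1, heme oxygenase, at -3.35 (adjusted p = 4.54e-10 and 5.56e-09). With an estimated correlation these 4 lists had an adjusted p = 0.00133 (histones), 0.0164 (respiratory chain), 0.154 (ribosomal proteins) and 0.543 (NRF2 and metal). Adjusted over the list alone, 37 histone, 24 respiratory chain, 33 ribosomal protein and 4 NRF2 and metal genes were higher.

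PPP1R15A, which directs dephosphorylation of eIF2 alpha, had 90.5 ± 4.95 TPM in inputs and 2.18 ± 0.0283 TPM in footprints (log2 difference -4.85, adjusted p = 4.88e-10). ATF4 stood at -1.97 (adjusted p = 1.23e-08), close to the median of all entries; on the mRNA scale it was 0.51 above its input (adjusted p = 0.000108). The nuclear RNA MALAT1 had 579 ± 36.9 TPM in inputs and 1.52 ± 0.0707 TPM in footprints (log2 difference -7.85, adjusted p = 2.71e-10). By the naming rule the highest were RNA5-8S5 (15.3, adjusted p = 4.16e-10) and copies of 5S ribosomal RNA, and the lowest were spike-ins such as ERCC-00002 (-13.3, adjusted p = 7.16e-11), which are added RNA, and RNVU1-7, a variant U1 RNA (-12.9, adjusted p = 3.81e-09). The other 17 lists were not called in vector cells (camera adjusted p from 0.0668 to 0.975). In QKI7 cells the same 4 lists were called, at relative medians of 4.20 (histones), 1.79 (respiratory chain), 1.79 (ribosomal proteins) and 0.87 (NRF2 and metal), with camera adjusted p = 1.4e-67, 4.13e-23, 2.76e-22 and 0.0337. These 4 had an adjusted p = 0.00121, 0.0226, 0.186 and 0.698 with an estimated correlation, and the other 17 lists were not called (camera adjusted p from 0.0552 to 0.983). Counts were 447 higher and 5220 lower in vector cells and 431 higher and 5272 lower in QKI7 cells; on the mRNA scale they were 1945 and 10035, and 1846 and 9765, with 472 genes in vector cells called in opposite directions on the 2 scales. Among lists not called, the relative median differed in sign from the mean or the test for 2 in RNA, 4 in footprints, 6 in translation efficiency, and 6 and 5 in footprint against input of vector and QKI7 cells.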

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

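The tests weighed here were chosen after the results were seen, except the comparison of translation factors with and without a 5' terminal oligopyrimidine tract, whose prediction was written before its value was seen. Its bound was edited after the value was seen: bounds of 0 and of 1 SD, the latter used here, count against the explanation, and one of 2 SD, also tried, would leave it undecided. The microRNA class of the small RNA comparison was redefined after its first value was seen. The genes listed in the last paragraph passed the interaction of library type and construct in limma on the deposited scale, and the lists there passed camera on that interaction at the preset correlation.

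Ribosomal protein mRNAs were lower in QKI7 inputs and in QKI7 footprints. Their RNA median relative to all genes was -0.62 on the mRNA scale, but such a median cancels any shift shared by all mRNAs, so it does not test the larger mRNA share of the QKI7 inputs, which by itself would raise these mRNAs. A bias of the QKI7 input libraries by length or sequence is argued against by the 46 spike-ins of at least 10 TPM, whose log2 ratios between constructs had an SD of 0.0633 over a range from -0.06 to 0.25; RNA quality before the spike-ins were added stays open. A fall of all mRNAs with a 5' terminal oligopyrimidine tract as a class was not seen in RNA among translation factors. The 12 with such a tract had a median RNA change of 0.01 against -0.08 for 24 others (one-sided permutation p = 0.836). The difference of 0.093 narrowly exceeds the SD of 0.0904 under permutation. By the bound of 1 SD this counts against the explanation, but a bound of 2 SD leaves it undecided. These few factors stand in for the whole class, so a class effect on RNA is not excluded. In footprints the medians were -0.30 against -0.17 (one-sided permutation p = 0.0417), so a class effect there may remain. An effect of QKI7 on these mRNAs, the biological explanation that the design names, remains open.

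Footprint-sized reads of RELN, GRK3, DICER1 and VAT1L were higher in QKI7 cells. They may come from translating ribosomes on these mRNAs or from another RNA that aligns to them. Of their footprint-to-input ratios, 3 of the 4 reached at least the 96.2th percentile of 819 entries with 1 TPM or more in footprints. RELN, with 0.0300 TPM of input, reached the 99.9th. Spike-ins, histone genes and small non-coding RNA were left out of these entries. Pseudogenes and long non-coding RNAs were kept, some of them footprint-rich, such as MTRNR2L6 and LOC105371730, so these are not ranks among mRNAs. What keeps the question open is that the table gives no positions of reads. A gain of all small RNA by the same factor in the QKI7 footprint libraries is argued against by the class ratios between constructs. These ranged from 1.12 for small nuclear RNA to 2.33 for microRNA, 2.09 times apart. With the wider classes used first, microRNA stood at 1.24, snoRNA at 1.86, and the range was 1.66. Every class compared rose, however, so a gain of small RNA that differs in size between classes is not excluded. Of the classes left out of the comparison, 7SL RNA stood at 1.27 and the mixed class of other small RNA at 0.953. No biological explanation was tested for these genes.

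Most translation efficiency calls were lower in QKI7 cells on the deposited scale. The larger mRNA share of the QKI7 inputs acting with the pseudocount may contribute. On the mRNA scale 19.1% of the calls were lower, against 85.8% as deposited. That scale centres the changes and tests other genes, so this comparison alone cannot separate the explanation from the choice of genes. With scaling alone changed, quantile normalization gave 56.2% and median-of-ratios scaling 34.6%; with the pseudocount alone changed, 0.1 gave 52.1% and 5 gave 87.0%; and a mean of at least 10 TPM alone gave 39.3%. A biological shift of translation remains untested, because no absolute scale for footprints was used here.

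For translation efficiency, higher values in QKI7 cells were 3.33 for SNORD32A, 2.79 for RELN, 2.40 for SNORA75, 2.35 for MIR663A, 2.23 for GRK3, 2.19 for MIR4449, 2.11 for MIR21, 2.09 for SNORD4A, 2.06 for SNORD63, 1.96 for SNORD68 and 0.31 for RELB. TNFAIP3 stood at 0.44 with the pseudocount, while its plain ratio of footprint to input TPM was 0.0199 in vector and 0.0184 in QKI7 cells. Lower values were -4.48 for QKI, -2.75 for SNORD57, -1.54 for MIR937, -1.51 for SNORD10, -1.20 for RPS13, -1.18 for RNA5-8S5, -1.14 for TUBA1C, -1.13 for MIRLET7D, -1.11 for SNORD116-4, -0.79 for HMGCS1, -0.77 for UBE2C, -0.70 for SQLE, -0.64 for DLGAP5, -0.61 for RRM1, -0.58 for both CENPE and MVD, -0.43 for G3BP1 and -0.32 for TEAD1 (0.49 on the mRNA scale), and TUBA1B fell by 1.00. The plain ratio of TEAD1 was 0.0230 in vector and 0.0284 in QKI7 cells, so its sign depends on the pseudocount. Translation does not apply to the non-coding RNAs among these genes. MIR937 and MIRLET7D were listed at 0 TPM in all footprint libraries and MIR21 in all inputs, so each value reflects 1 library type only. Leaving out 1 library gave -2.15 to -0.94 for MIR937, -1.57 to -0.78 for RNA5-8S5 and 1.46 to 2.91 for MIR4449. Footprints of HMGCS1, DLGAP5, RRM1, SQLE, MVD and CENPE were under 1 TPM in each library, so the pseudocount mutes their footprint changes. Values of SQLE, MVD and CENPE nearly mirror the input rise. Of 32 genes called for translation efficiency and followed by name, 18 passed without each library in turn. The lists stood at 0.28 for NF-kappaB, -0.19 for mitosis and -0.20 for cholesterol relative to all genes, with an adjusted p = 0.886, 0.935 and 0.886 with an estimated correlation, and 1 of the calls at the preset correlation held without each library in turn.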

How the results depend on the processing

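Scaling of the inputs to the spike-ins and the mRNA scale restricted to genes measured in both library types were chosen after seeing the data. Counts of calls followed the scale, pseudocount and filter; the filters test more or fewer genes, and for the others the cause was not tested. RNA level calls (2587) numbered 375 with a pseudocount of 0.1, 5153 without a filter, 156 at a mean of at least 10 TPM, 99 on the mRNA scale, 248 on it for genes measured in both types and 913 with only the 4 libraries compared. Footprint level calls (476) numbered 1124, 266, 207, 1999, 970 and 74 in the same order. Translation efficiency calls (1461) numbered 217, 819, 122, 241 and 333, without the last. Footprint against input calls in vector cells (5667) numbered 16314 without a filter, 487 at 10 TPM, 11980 on the mRNA scale and 2190 in both types, and in QKI7 cells (5703) 17195, 488, 11611 and 2124. Scaling to the spike-ins gave 1781 RNA calls. Leaving out each library in turn gave 1685 to 2603 RNA calls, 253 to 439 footprint calls, 269 to 1931 translation efficiency calls, and a correlation of RNA and footprint changes of 0.18 to 0.30; where a group keeps 1 library, it is assumed to vary like the others. That correlation (0.25) was 0.17 without a filter, 0.48 at 10 TPM and 0.10 on the mRNA scale, with the overexpressed QKI kept in each set.

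Directions turned for few results, and the cause was not tested beyond the change of scale. Footprint against input in vector cells became 0.51 for ATF4, 0.084 for G3BP1 and 0.17 for QKI on the mRNA scale, for all genes and for those measured in both types alike. TEAD1 translation efficiency became 0.49 on the mRNA scale, and the RNA change of ATF4 -0.23 with median-of-ratios scaling. The NRF2 and metal list of footprint against input became -0.34 without a filter and -0.82 at 10 TPM. Over the other alternatives, the ribosomal protein list kept its sign and its call in RNA (relative median -0.62 to -0.29) and footprints (-0.57 to -0.34), except with an estimated correlation (adjusted p = 0.153 and 0.0933). The cholesterol list did so in RNA (0.23 to 0.39), again except with an estimated correlation (adjusted p = 0.292).

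The labels do not say whether replicate numbers pair the libraries; deviations of same-numbered libraries correlated at -0.0881 to 0.125, which does not decide it. With the replicate number as a block, calls were 2305 for RNA, 423 for footprints and 1099 for translation efficiency, and with the culture as a block 1136 for translation efficiency. The search for QKI motifs and for their core motif was not run. TPM give no depth, so the precision of low footprint values is unknown.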

Other observations

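The families of small RNA tested here were chosen after the data were seen. Small nucleolar RNAs, which guide modification of ribosomal RNA, made up 0.365% ± 0.00129 of vector footprints and 0.678% ± 0.00277 of QKI7 footprints (SD, n = 2 each), and 0.0991% and 0.105% of the inputs. Of 79 box H/ACA RNAs tested, 47 were higher in QKI7 footprints and 0 lower by limma, with a median log2 change of 0.82; of 77 box C/D RNAs, 17 were higher and 1 lower, with a median of 0.58. The difference between these families was not tested. In inputs, the same 79 RNAs had 8 higher and 5 lower, with a median of 0.11. SNORA23 went from 160 ± 0.587 to 545 ± 28.2 TPM in footprints (log2 change 1.76, adjusted p = 0.000377), with 5.10 and 5.06 TPM in inputs, and SNORA75 from 80.3 ± 3.90 to 290 ± 3.55 TPM (log2 change 1.84, adjusted p = 0.000176).

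The spike-ins had 11.2 and 10.8 TPM in total in the vector footprints and 12.3 TPM in each QKI7 footprint library. Per TPM of spike-in, mRNA was 0.279 and 0.277 in vector inputs and 0.284 and 0.322 in QKI7 inputs. The marker lists of blood, epithelial and neural cells had 0 members at a mean of at least 1 TPM.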
